A study of Thermococcus onnurineus NA1 with 2 samples.

How the data were processed

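RNA was measured in 2 cultures of Thermococcus onnurineus NA1, a hyperthermophilic archaeon that produces hydrogen. Both cultures were harvested in exponential phase from medium MM1 supplemented with carbon monoxide. The wild type and the strain deleted for TON_1525, a gene for a DNA-binding protein of the Tfx family, were represented by 1 library each. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase I, rRNA was depleted with a kit made for human, mouse and rat RNA, and libraries were made with a stranded TruSeq total RNA kit.

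Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.32 and Bowtie2 2.2.4 were used. The same notes list the mouse genome build mm8, whereas the rows of the deposited table are genes of T. onnurineus, so no coordinates are given here. The counting tool, the use of strand and the treatment of fragments that map to several places are not given in the sources used here. The gene clusters described below include related hydrogenase and antiporter subunits, so their counts depend on that treatment.

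The deposited table gives, per the file headers, fragment counts, FPKM and TPM for each gene. The deposited counts were whole numbers per gene, not normalized. The deposited FPKM and TPM values were recomputed from the deposited counts and gene lengths without difference beyond rounding error, with the sum over the listed genes as the denominator. The authors thus left rRNA and tRNA out of the FPKM and TPM scale. Totals at the foot of the deposited table give, as percentages of mapped fragments, 83.4% rRNA in the wild type library and 84.3% in the deletion library, per the file headers.

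Gene names and gene order were taken from the table and from the RefSeq gene table of assembly ASM1836v1, in which 1947 of the 1975 rows found a match. Of these 1975 rows, 1932 were protein coding and 43 had no protein. The 1879 protein-coding genes with a mean TPM of at least 10 over both libraries were compared, and 53 protein-coding genes were below that level. For each gene the log2 ratio of (TPM + 1) in the deletion library over the wild type library was computed and centred on the median over the compared genes. That median was -0.03 before centring. A pseudocount of 1 understates the change of weakly expressed genes. Genes at least 2-fold higher or lower were counted.

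Because each strain had 1 library, no test was made and no p-value is given. The ratios have no replicate check, and they compare these 2 libraries, not the strains at large. Fold differences given with an interval were computed from the counts without a pseudocount and placed on the same centred scale. Their 95% intervals are exact conditional (Clopper-Pearson) intervals for the ratio of 2 counts, and exact Poisson intervals are given for the counts of TON_1525. All intervals cover counting error only. They treat fragments as independent, which PCR copies are not, so they may be too narrow even for that. A gene with 0 fragments in the deletion library was given a lower bound, set at 3 fragments in that library.

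Before the data were examined, the measure, the filter, the 2-fold threshold, 26 gene lists and the rule for named genes were fixed, together with most of the alternatives. The rule named TON_1525, the 10 genes with the highest and the 10 with the lowest log2 ratio, the highest and lowest member of each list, the genes on each side of TON_1525, and the members of each run of at least 3 consecutive genes at least 2-fold in 1 direction. It took in 121 genes. Genes named outside it were chosen after their values were seen. The CO dehydrogenase cluster, the formate hydrogenlyase cluster and the genes around TON_1525 were defined by locus tags, and the other lists by words in the product names. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The resulting percentile describes these libraries and takes no account of the agreement between neighbouring genes.

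Agreement between neighbouring genes was measured across genes and set beside 1000 shuffles of gene order. Neighbours were planned to be on the same strand, but without a strand column in the table they were taken in the order of their older locus tags, on either strand. Leaving rRNA and tRNA out of the TPM scale had been planned as an alternative and was already the deposited scale, so it was not run separately. The alternatives that were run used pseudocounts of 0.1 and 10, no filter or a mean TPM of at least 50, no centring or centring on a mean with 30% trimmed from each end, FPKM, counts scaled to library size, thresholds of 1.5-fold and 4-fold, unmatched random lists, and lists without their most extreme member. Subtraction of a trend with gene length in 10 bins, removal of the formate gene clusters from the TPM denominator and inclusion of the rows with no protein were added after seeing the data.

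The calculation was tested on simulated data before use, with Poisson counts for the 1879 genes at the depth of both libraries. Of 50 genes lowered 3-fold, 99.2% on average passed 2-fold, and of 50 genes raised 3-fold, 100% did. At 8-fold, 100% passed in each direction. Of the unchanged genes, 0.0478% passed. These simulations held counting error alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.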

Results

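The transcriptome of T. onnurineus NA1 growing with carbon monoxide was compared between the wild type and the TON_1525 deletion strain, to ask which genes differ in expression when this DNA-binding protein is missing. The series title ties the deletion to increased hydrogen production. The wild type library held 4905193 fragments on listed genes, 14.2% of its 34511899 mapped fragments, and the deletion library held 3798634, 13.2% of its 28734084. The median gene had 817 fragments in the wild type library and 658 in the deletion library.

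The deleted gene itself was lower in the library of the deletion strain, but it was not at 0. TON_1525 had 2614 fragments in the wild type library (95% Poisson interval 2515 to 2716) and 272 in the deletion library (241 to 306). Its level was 1004 TPM against 124 TPM, which was 7.96-fold lower (95% counting interval 7.03 to 9.06). The 9 measured genes around it, between TON_1520 and TON_1529, were all within 2-fold. Their median log2 ratio was 0.12, at percentile 78.5 of the matched random lists. They ran from -0.45 for TON_1521, which codes for a DUF3213 protein, to 0.35 for TON_1523, annotated as an effector of murein hydrolase. TON_1530 was not analysed here.

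Most transcripts were at similar levels in both libraries, while the genes for formate-dependent hydrogen production were far lower in the deletion library and those for carbon monoxide oxidation and the membrane-bound hydrogenase were higher. Of the 1879 genes compared, 59 were at least 2-fold higher in the deletion library and 66 were at least 2-fold lower. The remaining 1754 genes, 93.3%, were within 2-fold, and the middle part of all ratios, from the lower to the upper quartile, ran from -0.30 to 0.25 on the log2 scale. Of the lower genes, 25 were at least 32-fold lower. The counting interval excluded no change for all 125 genes past 2-fold, and for 1261 of the 1879 genes in all, and it leaves out differences between cultures, which 1 library per strain does not measure. Genes past 2-fold often lay side by side. They formed 7 runs of consecutive genes with 71 members, 4 of them lower and 3 higher, and 54 genes past 2-fold lay elsewhere.

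**Figure D1:**
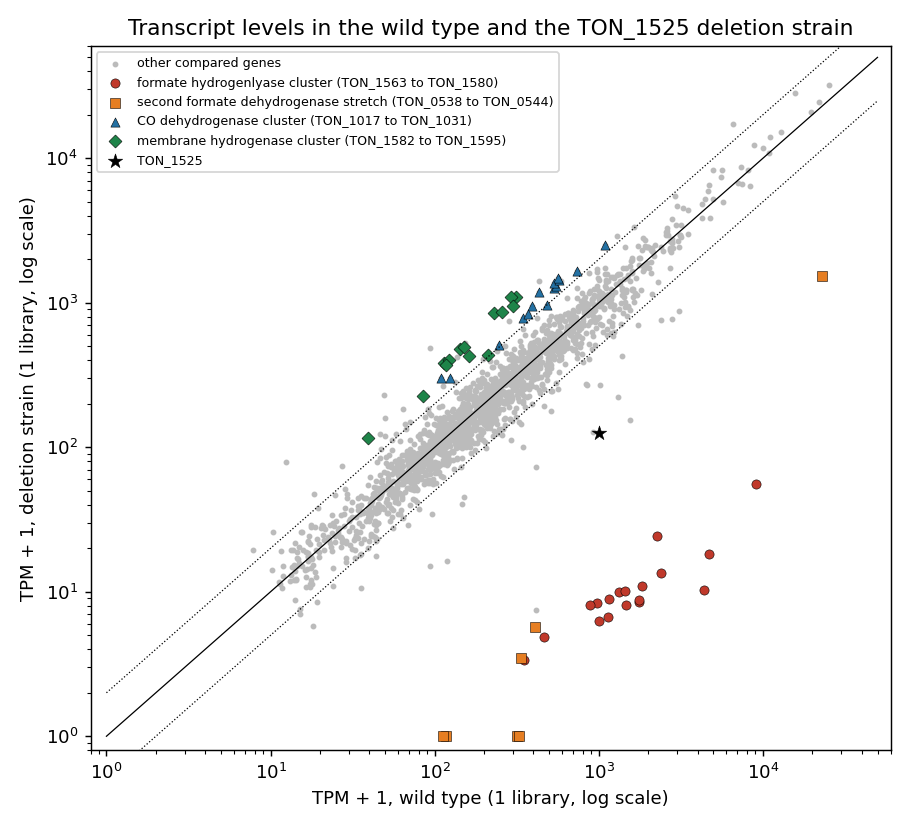
TPM + 1 of each compared gene in the wild type library (horizontal, log scale) and in the deletion library (vertical, log scale), 1 library per strain. The solid line marks equal levels and the dotted lines 2-fold differences, without centring. The formate hydrogenlyase genes lie far below the diagonal, the CO dehydrogenase and membrane hydrogenase genes lie above it, and TON_1525 is at 1004 and 124 TPM.

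The formate hydrogenlyase cluster, TON_1563 to TON_1580, showed the lowest ratios of any list. It codes for a formate dehydrogenase, a membrane hydrogenase, a formate transporter and a cation/proton antiporter, which together allow growth on formate with release of hydrogen. All 18 of its genes were at least 2-fold lower in the deletion library, with a median log2 ratio of -7.30 (158-fold lower) at percentile 0 of the matched random lists. The formate dehydrogenase alpha subunit gene TON_1563 had 59554 fragments in the wild type library and 184 in the deletion library, 268-fold lower (95% counting interval 232 to 312). The iron-sulfur protein gene TON_1564 next to it had the lowest log2 ratio of all compared genes at a pseudocount of 1 TPM, -8.72, with 12969 and 23 fragments. The hydrogenase large subunit gene TON_1569 was 188-fold lower (156 to 229), and the formate transporter gene TON_1573 was 162-fold lower (144 to 182). The antiporter gene TON_1580 had the highest ratio of the list and was still 95.8-fold lower (82.8 to 112). TON_1576, coding for a DUF4040 antiporter subunit, had 526 fragments in the wild type library and 3 in the deletion library, a ratio of 145-fold with a wide counting interval of 49.5 to 707.

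The low stretch extended past the list on both sides, from TON_1559 to TON_1581, with 23 genes and a median log2 ratio of -7.02 (129-fold lower). Its members took 5.77% of the gene fragments in the wild type library and 0.214% in the deletion library. The first genes of the stretch showed smaller differences. TON_1559, annotated as a coenzyme F420 hydrogenase, was 2.42-fold lower (2.34 to 2.51), and TON_1562, for the formate dehydrogenase accessory protein FdhD, was 7.16-fold lower (6.51 to 7.88). At the other end TON_1581, for the molybdenum cofactor guanylyltransferase MobA, had a log2 ratio of -5.77, and the adjoining antiporter gene TON_1582 had one of 1.07.

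Another formate dehydrogenase stretch, TON_0538 to TON_0544, formed a run of 7 lower genes. It was not a fixed list, and its bounds come from these ratios, so all 7 are lower by definition. The median log2 ratio of the run was -6.78 with a pseudocount of 1 TPM. With the genes at 0 set to their bounds, which hold no pseudocount, it was -6.58 (95.9-fold lower). That value is the pseudocount ratio of TON_0542, which was 134-fold lower (78.5 to 253) without a pseudocount. In the deletion library 0 fragments were counted for 4 of these genes. The formate dehydrogenase alpha subunit gene TON_0539 had 3808 fragments in the wild type library and was at least 1052-fold lower. The iron-sulfur protein gene TON_0540 had 942 and was at least 260-fold lower, the formate transporter gene TON_0538 had 678 and was at least 187-fold lower, and TON_0541, for another iron-sulfur protein, had 248 and was at least 68.5-fold lower. TON_0542 and TON_0543 kept 13 and 12 fragments in the deletion library, against 2109 and 1225 in the wild type library. The last gene of the stretch, TON_0544, codes for an iron-containing alcohol dehydrogenase. It was among the most abundant transcripts of the wild type library at 22914 TPM and stood at 1522 TPM in the deletion library, 14.8-fold lower (14.5 to 15.1).

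The cluster for carbon monoxide oxidation, TON_1017 to TON_1031, was higher throughout. It codes for a carbon monoxide dehydrogenase coupled to a hydrogenase and an antiporter, the system by which this organism gains energy from carbon monoxide with release of hydrogen. All 15 genes were at least 2-fold higher in the deletion library, with a median log2 ratio of 1.29 (2.44-fold) at percentile 100 of the matched random lists, and their share of gene fragments was 0.880% in the wild type library and 2.28% in the deletion library. The carbon monoxide dehydrogenase catalytic subunit gene TON_1018 had 12142 and 23596 fragments, 2.34-fold higher (2.29 to 2.40). The hydrogenase large subunit gene TON_1023 was 2.29-fold higher (2.22 to 2.36). The ratios of the list were lowest at 1.03 for the iron-sulfur protein gene TON_1017 and highest for TON_1020, a CooT family nickel-binding protein gene that was 2.84-fold higher (2.29 to 3.53). With the trend with gene length subtracted, TON_1017 was at 0.93 and TON_1025 at 0.90, under 2-fold.

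The membrane-bound hydrogenase and its antiporter subunits, TON_1582 to TON_1595, were higher by more. They form a run whose bounds come from these ratios, so all its genes are higher by definition. The 14 genes had a median log2 ratio of 1.74 (3.35-fold higher), and their share of gene fragments was 0.216% in the wild type library and 0.800% in the deletion library. The hydrogenase gene TON_1593 was 3.54-fold higher (3.38 to 3.71), the membrane subunit gene TON_1594 3.83-fold higher (3.62 to 4.04) and the antiporter gene TON_1589 3.77-fold higher (3.59 to 3.96). TON_1582 had the lowest ratio of this run and was at 0.97, under 2-fold, with the trend with gene length subtracted.

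**Figure D2:**
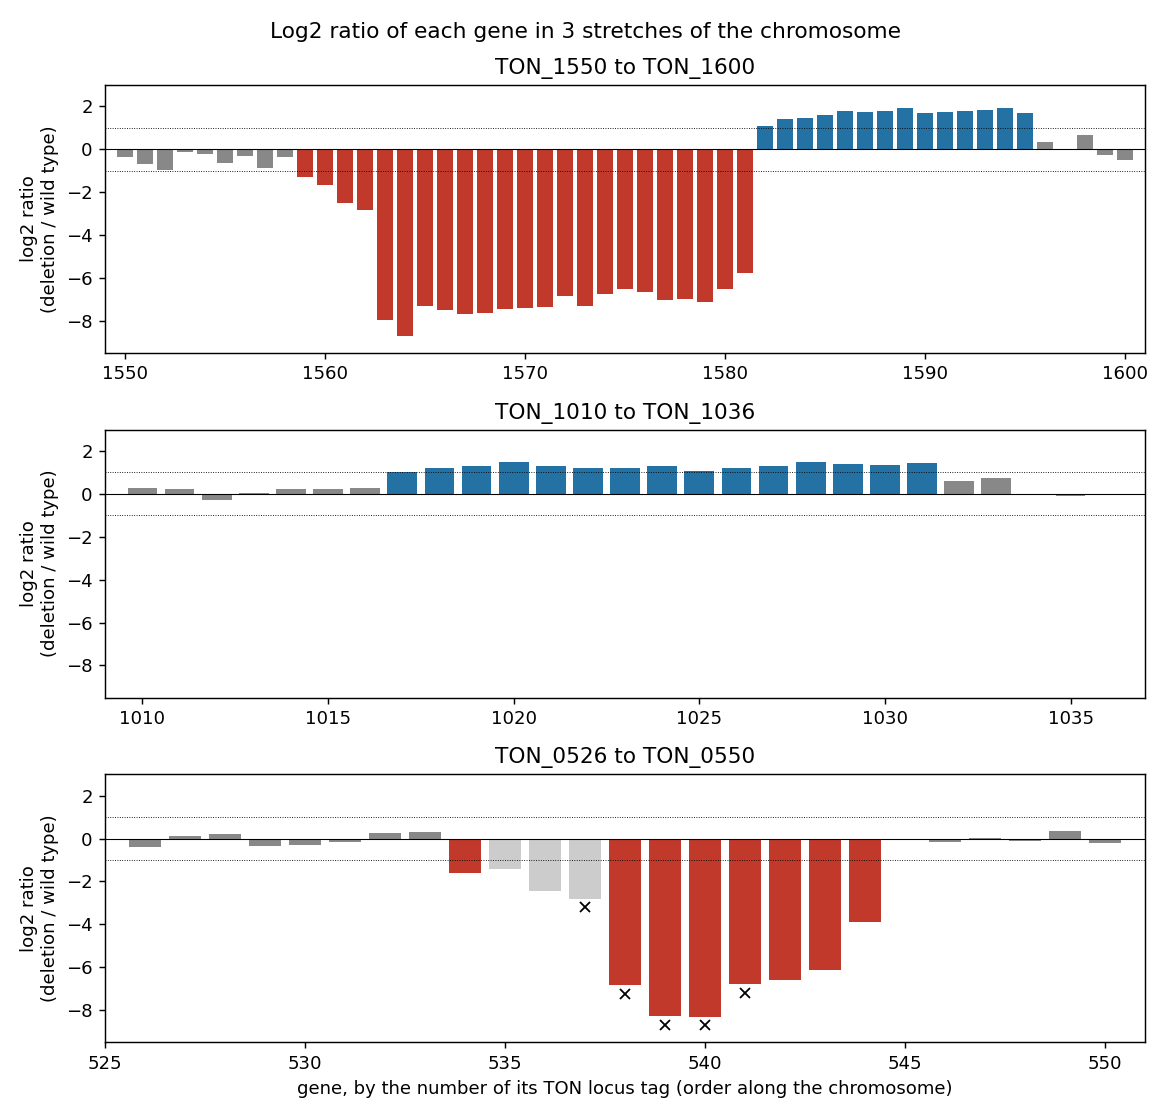
Log2 ratio of the deletion library over the wild type library (bars, with a pseudocount of 1 TPM) for each gene in 3 stretches of the chromosome, ordered by locus tag. Red bars are at least 2-fold lower, blue bars at least 2-fold higher and dark grey bars within 2-fold, light grey bars are below a mean TPM of 10, dotted lines mark 2-fold, and a cross marks 0 fragments in the deletion library. The ratio turns from -5.77 to 1.07 between TON_1581 and TON_1582.

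Lists defined by product name that spanned these clusters held members in both directions. Of 22 hydrogenase subunit and maturation genes, 3 were at least 2-fold higher and 7 at least 2-fold lower, with a median log2 ratio of -0.03 at percentile 38.1. They ran from -7.62 for the hydrogenase gene TON_1568 of the formate hydrogenlyase cluster to 1.82 for TON_1593 of the membrane-bound hydrogenase. The words that define this list leave out subunits that went either way. TON_1024 and TON_1591, whose ortholog groups are hydrogenase small subunits, were at 1.29 and 1.73. TON_1572, whose ortholog group is a formate hydrogenlyase subunit, was at -6.85. The counts of 3 and 7 therefore depend on the naming and do not cover all hydrogenase subunits. Of 35 cation/proton antiporter genes, 12 were at least 2-fold higher and 5 at least 2-fold lower, with a median of 0.06 at percentile 73.2. They ran from -7.14 for TON_1579 to 1.91 for TON_1589.

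Transport genes made up 2 of the other runs. The run TON_0158 to TON_0162, a branched-chain amino acid ABC transporter, was higher in the deletion library with a median log2 ratio of 1.54 (2.90-fold) over 5 genes. Its permease gene TON_0158 was 3.53-fold higher (3.28 to 3.81) and its substrate-binding protein gene TON_0162 3.35-fold higher (3.21 to 3.48). The run TON_0296 to TON_0299, annotated in part as an iron ABC transporter, was lower with a median log2 ratio of -2.55 (5.86-fold) over 4 genes. The substrate-binding protein gene TON_0296 was 5.66-fold lower (5.19 to 6.19), the permease gene TON_0297 had a log2 ratio of -2.61, the ATP-binding protein gene TON_0298 one of -2.83, and TON_0299, for a hypothetical protein, one of -1.73. Beyond TON_0300 followed the run TON_0301 to TON_0303, which starts with a molybdopterin-dependent oxidoreductase gene. Its 3 genes had log2 ratios of -1.62, -1.74 and -1.48 in locus tag order. TON_0300 itself, between these runs, had the highest ratio of all compared genes at a pseudocount of 1 TPM, 2.70, on only 25 fragments in the wild type library and 145 in the deletion library. At a pseudocount of 10 TPM it came after TON_0484. Among all 52 ABC transporter genes compared, 5 were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.07 at percentile 89.5.

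Besides TON_0300, the transport genes TON_0484 and TON_0901 were the only genes outside the runs among the 10 highest ratios. TON_0484, for a uracil-xanthine permease, was 5.35-fold higher (4.93 to 5.82), and TON_0901, for a symporter of dicarboxylates or amino acids, was 4.78-fold higher (4.26 to 5.38). Besides these and TON_0300, the other 7 of the 10 highest ratios were those of TON_0158 and of the membrane-bound hydrogenase genes TON_1586, TON_1588, TON_1589, TON_1592, TON_1593 and TON_1594. The 10 lowest at a pseudocount of 1 TPM were those of TON_0539, TON_0540, TON_1563, TON_1564 and TON_1566 to TON_1571. This order depends on the pseudocount, and at 0.1 TPM the 4 genes at 0 fragments, TON_0538 to TON_0541, came before TON_1564.

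ATP synthase genes and most of the listed motility genes were lower by smaller factors. All 9 ATP synthase genes, which code for the ATP-forming membrane enzyme, were lower in the deletion library, 2 of them at least 2-fold, and the median log2 ratio of -0.89 (1.86-fold lower) lay at percentile 0.015. The random lists draw scattered genes, so the percentiles of lists of adjacent genes, such as this one and the fixed clusters, take no account of the agreement between neighbours. Subunit D, TON_1754, was 2.06-fold lower (1.95 to 2.18) and subunit B, TON_1753, was 1.62-fold lower (1.58 to 1.66). Of 22 archaellum and chemotaxis genes, a group picked by product name that serves swimming, 21 were lower and 3 of these at least 2-fold, with a median of -0.56 (1.47-fold lower) at percentile 0. The flagellin gene TON_1189 was 3.64-fold lower (3.02 to 4.40), while TON_1344 was at 0.20. The product name of TON_1344 is that of the flagellar protein FliE, but its ortholog group is annotated as dephospho-CoA kinase, which has no known part in swimming. The 4 maltodextrin and glucan genes had a median of -0.77 at percentile 0.255, from -0.80 for the alpha-amylase gene TON_1451 to -0.21 for the neopullulanase gene TON_1796.

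Amino acid biosynthesis genes went both ways. Of 20 genes, 12 were higher, 2 of these at least 2-fold, and 8 were lower. Their median log2 ratio of 0.33 lay at percentile 99.99, but its 95% interval across these genes, from order statistics, ran from -0.36 to 0.49 and included 0. Such an interval treats genes as independent, which neighbouring genes are not. It describes the spread within a list and does not measure differences between cultures. The cysteine synthase family gene TON_1004 was 2.29-fold higher (2.22 to 2.36), and the glutamate synthase gene TON_1376 was 1.83-fold lower (1.70 to 1.98). Smaller medians outside the middle 95% of matched random lists were found for 4 more lists, and the same interval included 0 for each of them but the hypothetical proteins. The 22 DNA replication and repair genes had a median of -0.29 at percentile 0.27, from -0.61 for the DNA polymerase II large subunit gene TON_1642 to 0.33 for the topoisomerase gene TON_0763. The 62 ribosomal protein genes had a median of -0.09 at percentile 0.75, from -0.88 for L14 (TON_0076) to 0.75 for L35ae (TON_0649), and lay at percentile 8.75 of unmatched lists. The 54 transcription regulator and DNA-binding protein genes had a median of 0.14 at percentile 98.1, with TON_1525 lowest and the PadR family gene TON_0994 highest at 1.35, on 25 and 56 fragments. The 369 hypothetical protein genes had a median of 0.06 at percentile 99.9, with TON_1572 of the formate hydrogenlyase cluster lowest at -6.85 and TON_0300 highest. The ratio went down with gene length (Spearman -0.226 across the 1879 genes, which are not replicates), from a median of 0.17 for the shortest of 10 length bins to -0.21 for the longest. With that trend subtracted, the percentiles among 2000 lists were 10.8 for DNA replication and repair, 69.9 for transcription regulators, 76.6 for hypothetical proteins and 0 for ribosomal proteins.

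**Figure D3:**
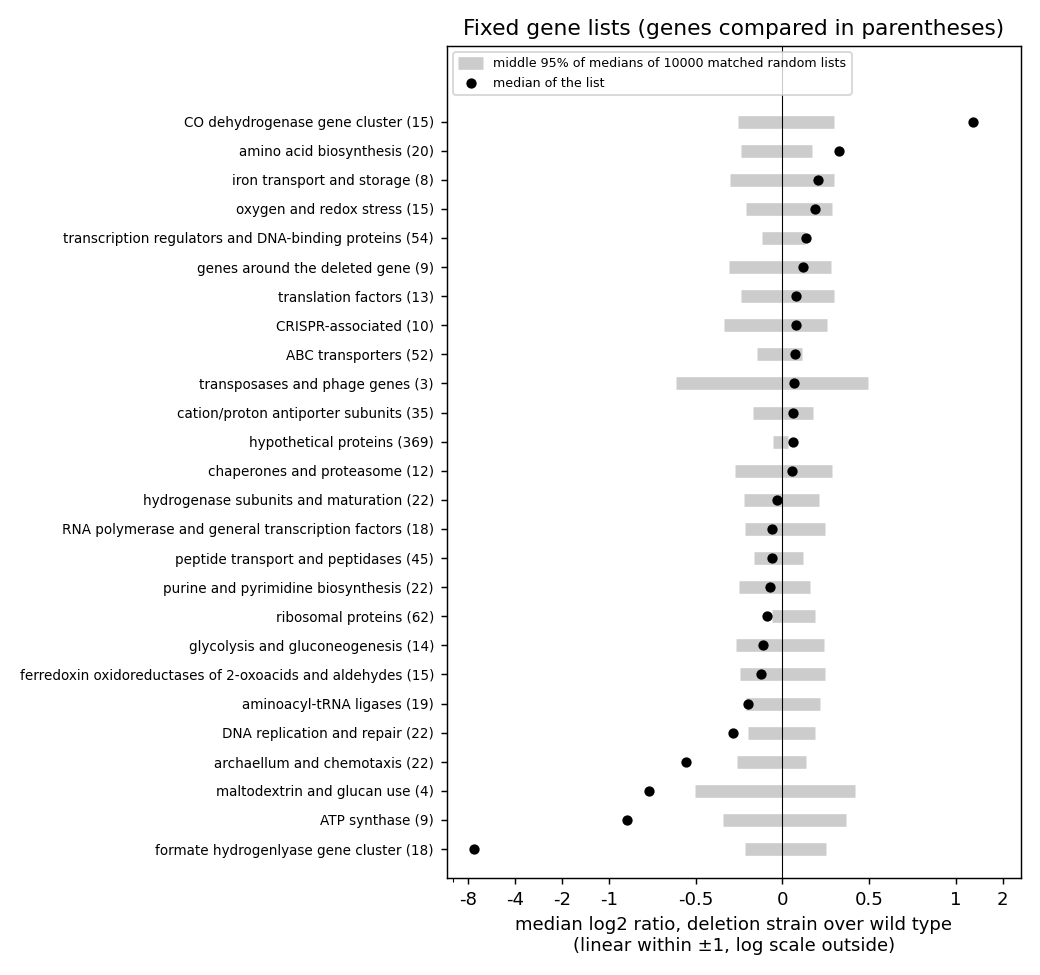
Median log2 ratio of the deletion library over the wild type library for each of the 26 lists (points, number of compared genes in parentheses), on an axis that is linear within 1 of 0 and logarithmic outside. Grey bars span the middle 95% of medians of 10000 random lists of the same size and expression. The formate hydrogenlyase cluster is at -7.30, ATP synthase at -0.89 and the CO dehydrogenase cluster at 1.29.

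Other basic functions were inside the middle 95% of the matched random lists. The 12 chaperone and proteasome genes had a median of 0.06 at percentile 59.4, although the thermosome subunit gene TON_0707, for the main chaperonin of archaea, was 3.11-fold lower (3.02 to 3.20), and the prefoldin gene TON_0914 was highest at 0.24. The 22 purine and pyrimidine biosynthesis genes had a median of -0.07 at percentile 35.1, between -0.90 for the orotidine-5'-phosphate decarboxylase gene TON_1251 and 1.71 for TON_1438, the regulatory subunit of aspartate carbamoyltransferase. The 19 aminoacyl-tRNA ligase genes had a median of -0.20 at percentile 2.95, from -0.53 for the leucine enzyme (TON_0141) to 0.19 for the tyrosine enzyme (TON_0981). The 13 translation factor genes were at 0.08 and percentile 60.5, from -0.04 for IF-6 (TON_1107) to 0.73 for eIF-1A (TON_0767). Of these, 11 were higher and 2 lower, and the order-statistic interval of their median, 0.015 to 0.245, left out 0. The 18 genes for RNA polymerase and general transcription factors were at -0.06 and percentile 21.5, from -0.55 for polymerase subunit H (TON_0216) to 0.63 for subunit P (TON_0454).

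Lists for central metabolism, transport and stress also lay inside that range. The 14 glycolysis and gluconeogenesis genes had a median of -0.11 at percentile 18.2, from -0.88 for the phosphorylating glyceraldehyde-3-phosphate dehydrogenase gene TON_0639 to 0.20 for the glucose-6-phosphate isomerase gene TON_0247. Of these, 12 were lower and 2 higher, and the order-statistic interval of their median, -0.51 to -0.04, left out 0. The 15 ferredoxin oxidoreductase genes had a median of -0.13 at percentile 12.98, from -0.87 for TON_0749, an aldehyde enzyme, to 0.95 for TON_0583, a 2-oxoacid enzyme. The 45 peptide transport and peptidase genes were at -0.06 and percentile 22.4, between -0.98 for the metalloprotease gene TON_1276 and 0.59 for the metallopeptidase gene TON_1032. The 8 iron transport and storage genes were at 0.20 and percentile 89.6, between -0.37 for the ferrous iron transport gene TON_0657 and 0.61 for the ferritin family gene TON_0410. The words that define this list do not take in the ABC transporter genes TON_0296 to TON_0298, whose permease gene TON_0297 is annotated for iron and was at -2.61. The 15 oxygen and redox stress genes were at 0.19 and percentile 86.0, between -0.54 for the glutaredoxin gene TON_0472 and 0.61 for the NADH oxidase gene TON_1128. The 10 CRISPR-associated genes were at 0.08 and percentile 76.2, and 2 Cas6 genes marked their ends, TON_0326 at -0.69 and TON_0892 at 0.63. The 3 transposase and phage genes ran from -1.07 for TON_1244 to 0.56 for the integrase gene TON_1378, with a median of 0.07 at percentile 64.9, and TON_1244 was at -0.97 with the length trend subtracted.

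Neighbouring genes, which are often cotranscribed in archaea, had similar ratios. Over 1766 pairs of adjacent genes, the log2 ratios had a Pearson correlation of 0.836 and a Spearman correlation of 0.442, across genes, which are not independent replicates. The highest values among 1000 shuffles of gene order were 0.0939 and 0.0745. Outside the 7 runs, 1691 pairs gave 0.364 and 0.381.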

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

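The tests of depth, residual level, loss from the chromosome, carry-over, fragments shared with TON_1524, freed fragments and gene length were chosen after the log2 ratios had been seen, and the question of single cultures follows from the design.

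A row with no protein stood out because it lies outside the protein-coding comparison and was well above the level that 0 fragments allow. TON_RS05225, whose locus tag falls within the carbon monoxide dehydrogenase cluster between those of TON_1023 and TON_1024, was at 628 TPM in the wild type library and 1453 TPM in the deletion library, 2.36-fold higher (95% counting interval 2.228 to 2.495). Another row with no protein, TON_RS10270, went the other way with 98 and 11 fragments, 7.38-fold lower (3.95 to 15.3).

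TON_0537 to TON_0541, a stretch of 5 genes with consecutive older locus tags, had 0 fragments in the deletion library against 5716 in the wild type library. Over all 1975 rows, 6 were at 0 fragments in the deletion library and 1 in the wild type library. The lower depth of the deletion library does not account for the lack of fragments on these 5 genes, since 4427 would be expected at equal levels. The stretch was also below the remainder seen in other strongly lowered genes, since 10.1 fragments would be expected even at the lowest share that any of 21 other genes at least 32-fold lower kept, 0.177% for TON_1564. Loss of this stretch from the chromosome of the sequenced strain predicts 0 fragments on all 5 genes, and so does transcription that depends fully on TON_1525, so these cannot be told apart from RNA alone. A biological effect of the deletion on this stretch may therefore be present, but it remains a hypothesis.

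TON_1525 kept 272 fragments in the library of the strain that should lack it. Wild type cells or reads in that library do not account for them. TON_0537 to TON_0541 had 0 fragments there. With 3 taken as the bound, carry-over is at most 0.0525% of the count in the wild type library. This allows 1.37 fragments on TON_1525. This limit assumes that any wild type cells there expressed the stretch as the wild type library did. TON_1524 had 308 fragments in the wild type library and 269 in the deletion library, so fragments shared with it could make up at most 269 of the 272. That would need every fragment on TON_1524 to lie on TON_1525 too. A smaller shared part cannot be told apart from a remnant of TON_1525 that is still transcribed, since totals per gene do not show where fragments lie. Sharing with TON_1526, on the other side, was not tested. No biological explanation was tested.

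The carbon monoxide dehydrogenase and membrane-bound hydrogenase clusters, 29 genes, had a median log2 ratio of 1.43. The formate gene stretches were taken as TON_0534 to TON_0544 and TON_1559 to TON_1581. They held 9.32% of the gene fragments in the wild type library and 0.459% in the deletion library. The alcohol dehydrogenase gene TON_0544 alone had 164838 of those in the wild type library. Fragments freed there do not account for the median of the 29 genes. The other 1848 genes, which include these 29, had an uncentred median log2 ratio of -0.0211. A trend with gene length does not account for the median of the 29 genes as a whole. It was 1.44 with that trend subtracted, although TON_1017, TON_1025 and TON_1582 were then under 2-fold. A difference between single cultures cannot be told apart from an effect of the deletion with 1 library per strain. An effect of the deletion on both clusters may be proposed only as a hypothesis.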

How the results depend on the processing

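Removal of the length trend, of the formate genes from the TPM scale, and inclusion of rows with no protein were chosen after seeing the data. Of the 14 alternative settings, those other than thresholds gave 52 to 60 genes at least 2-fold higher and 58 to 78 at least 2-fold lower. At 1.5-fold they numbered 144 and 202, and at 4-fold 3 and 33, as the thresholds themselves imply. FPKM, counts scaled to library size and the denominator without the formate genes rescale whole libraries. Apart from the pseudocount, centring removes that change. The centring choices shift all ratios alike, by -0.03 without centring. Agreement under these settings was therefore largely fixed in advance. Of 1205 values for named genes, 0 reversed. Of 818 values for the 82 named genes past 2-fold, 813 stayed past it in the same direction. The 5 others were those of TON_1017, TON_1025, TON_1244 and TON_1582 without the length trend, and of TON_0994 (log2 ratio 0.87) with a pseudocount of 10. Of 286 list medians, 2 moved beyond their interval. The formate hydrogenlyase median was -6.20 with a pseudocount of 10, which compresses ratios of genes left at a few TPM. The hypothetical protein median was 0.000138 without the length trend. That setting differs only in subtracting the median ratio of each length bin, which accounts for the move. The correlation of neighbouring genes was 0.852 with a pseudocount of 0.1, 0.811 with a pseudocount of 10 and 0.875 at a mean TPM of at least 50, and the cause was not tested. At a mean TPM of at least 50, transcription regulators lay at percentile 97.2. No paired analysis was possible because each strain had 1 library, and for the same reason no library could be left out. Depth limits genes with few fragments such as TON_0300 and TON_0994.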

Other observations

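The genes and the set described here were chosen after their values were seen. Some genes annotated for the molybdenum cofactor were lower in the deletion library also outside the formate clusters. Of 14 genes outside the runs whose product names mention molybdopterin, molybdenum or a Moa protein, 4 were at least 2-fold lower, 0 were at least 2-fold higher and 10 were within 2-fold. The log2 ratios of 5 of the 14 were above 0, up to 0.37 for TON_1623. The 14 include TON_0828, for an oxidoreductase that uses the cofactor, and TON_1808, for a MoaD/ThiS family protein, which can serve thiamine synthesis instead, both within 2-fold. The cyclase gene moaA (TON_1410), for the first step of the pathway, was 3.69-fold lower (95% counting interval 3.47 to 3.93). The molybdenum insertion gene TON_1091 was 2.98-fold lower (2.82 to 3.15), and the adjacent genes TON_0690 and TON_0691 were 2.37-fold and 2.04-fold lower. Next to the formate dehydrogenase genes, the hydrogenase gene TON_0534 had 130 fragments in the wild type library and 31 in the deletion library. TON_0535 had 44 and 11, TON_0536 had 37 and 2, and TON_0537 had 40 and 0, all 3 below a mean TPM of 10.

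Several abundant transcripts of other functions were also lower in the deletion library. The slipin family gene TON_1058 was 9.90-fold lower (9.12 to 10.8), more than any other compared gene outside the runs. TON_1249, for inositol-3-phosphate synthase, and TON_0659, for an NDP-sugar synthase, were 3.45-fold lower (3.35 to 3.56) and 3.50-fold lower (3.39 to 3.62). Among genes higher in the deletion library were the phosphate transporter genes TON_1475, 3.16-fold (2.91 to 3.44), and TON_0616, 2.83-fold (2.31 to 3.48). Both subunit genes of aspartate carbamoyltransferase, an early enzyme of pyrimidine synthesis, were higher, TON_1437 by 2.17-fold (1.91 to 2.47) and TON_1438 by 3.31-fold (2.70 to 4.07). The nucleobase permease gene TON_1957 was higher by 2.71-fold (2.21 to 3.34). Of all 22 listed purine and pyrimidine biosynthesis genes, 9 were higher and 13 lower, with a median log2 ratio of -0.07. TON_0510, for a protein with a class III signal peptide, was at 6558 TPM in the wild type library and 17226 TPM in the deletion library. Its ortholog group is annotated as pilin or flagellin.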
